A study of Homo sapiens with 2 samples.

How the data were processed

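RNA of 2 cultures of the human glioblastoma line A172 was sequenced, per the labels: the parental line, labelled as kept without temozolomide (TMZ), and a resistant clone selected with that drug, labelled as kept with it. Each group held 1 library, so clone, selection and drug exposure differ together. The labels name a stranded mRNA library kit. The aligner, the quantification tool, the annotation, the genome build and whether strand was used in counting are not given in the sources used here.

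The deposited table gives FPKM (fragments per kilobase of transcript, scaled to sequencing depth) for each library, per the file headers, and the scaling behind those values is not stated. It also holds the authors' log2 ratio of resistant over parental, with p-values and q-values of their comparison, per the file headers, and their test is not stated. The table lists 15603 genes by Ensembl identifier. No gene was listed at 0 in both libraries, and the higher of the 2 values was at least 0.544 FPKM for every gene, so the table appears to have been filtered before it was deposited. Exactly 0 was listed for 111 genes in the parental and for 182 in the resistant library. Such a 0 can be a failed estimate, since IAH1 and ZNF512, which most cells express and which were chosen after their values were seen, were listed at 5.91 and 6.10 FPKM in the parental library and at 0 in the resistant one. For a gene at 0 in 1 library both values are given and no fold is printed. Such genes still enter the calls and medians, where their fold depends on the pseudocount: they make up 23 of the 640 higher calls, MGMT among them, and 62 of the 532 lower ones. For the 15310 genes above 0 in both libraries, the authors' log2 column equalled log2 of the FPKM ratio within 0.001. Spreadsheet software had turned 19 gene names into dates, and these genes were kept under their identifiers.

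Sequencing depth is unknown, since only FPKM were used here. As a check, low values of single-exon genes were multiplied by gene length and searched for steps of 1 fragment. At the best step size, 30.8% of such values in the parental and 32.9% in the resistant library lay within 0.1 of a whole multiple, where 20% would by chance at any 1 step size. No fragment counts were therefore recovered, and no counting interval is given.

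GENCODE release 29 (GRCh38) held 15531 of the identifiers. The locus given in the table had the same start in 63.3% of them and contained the GENCODE gene in 96.8%, so GRCh38 coordinates from that release are given. Loci of overlapping genes were merged in the table, with 7088 genes sharing a locus. Transcript length and GC content came from the same release and covered 99.6% of the tested genes.

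The fold of a gene was log2 of (resistant FPKM + 1) over (parental FPKM + 1). The pseudocount of 1 understates the change of genes with low values. Genes with 1 or more FPKM in either library were tested, and a gene was called higher or lower in the resistant library when the fold was at least 2 (log2 fold of 1 in size). No p-value was computed, because 1 library per group leaves no replicate spread. For each of 40 gene lists fixed before the data were examined, the members called higher, lower or neither were counted. For lists with 5 or more measured members, the median log2 fold was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list or chromosome is said to lie outside the random band when its median is beyond the middle 95% of these, which describes these libraries and tests no condition. Chromosome medians were treated the same way, and windows of 100 adjacent genes were computed for the closing part.

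Named genes were set by a rule written before the data were examined: MGMT and a few mismatch repair genes, among them MSH6 and PMS2, always, the 10 genes highest and the 10 lowest in the resistant library among called genes with 5 or more FPKM in the higher library, up to 4 members of each list with the largest folds, and the 5 most abundant genes of each library. Genes without a symbol, XIST and Y-linked genes were left out, and a few genes that the rule names are not reported here. Any other gene named is said to have been chosen after its values were seen.

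The calling rule and the random lists were tested on simulated data, with the mean levels of the real genes, a log2 noise SD of 0.50 set to the real spread of folds, and 50 genes changed at each size. Among 13614 simulated genes, 18% of those changed 1.5-fold, 76% of those changed 2.5-fold, 98% of those changed 4-fold and 100% of those changed 8-fold were called with the right sign. Of the unchanged genes, 2.60% were called. Of 400 unchanged lists of 24 genes, 3% lay outside the band. The changed genes were not drawn from those with the lowest mean levels, whose folds the pseudocount shrinks most. The noise was independent between genes and equally wide at every level. These shares therefore describe the simulation and are not error rates of the real data.

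Alternatives were median centring, upper quartile scaling, no filter, a filter of 5 FPKM, pseudocounts of 0.1 and 0.01, thresholds of 1.5-fold and 4-fold, the authors' q-values, matching on length or GC content, and leaving out genes at 0 in 1 library. The computations used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3, and the plots matplotlib 3.10.9.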

Results

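The data describe gene expression in A172, an established human glioblastoma cell line, and in a clone of it selected for resistance to temozolomide, the alkylating drug used against this tumour. Expression was measured by RNA sequencing with a stranded mRNA library kit in 2 libraries, 1 parental and 1 resistant. There were no replicates, so every difference below is a difference between these 2 libraries and has no replicate check. Depth per library is unknown, because the values are FPKM. The FPKM summed to 299594 in the parental and 323932 in the resistant library, with medians of 6.84 and 7.14. The same 5 genes were most abundant in both libraries: MALAT1 (7785 FPKM parental, 7229 resistant), RN7SL2 (5293 and 6750), SPARC (2854 and 3856), 7SK (2593 and 3484) and ACTB (2333 and 2515). They made up 6.96% of the parental and 7.36% of the resistant sum. RN7SL2 has near-identical copies in the genome, so its value is uncertain. Across genes, log2(FPKM + 1) of the libraries correlated with Pearson's r of 0.94, and genes are not independent replicates.

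The comparison asks which genes differ in level between the parental line and its resistant clone. MGMT, which removes the alkyl group that temozolomide leaves on guanine, was listed at 0 FPKM in the parental library and at 5.16 in the resistant one. The lists of p53 targets, of the unfolded protein and ATF4 response and of the NRF2 response had higher medians in the resistant library, with CDKN1A, TRIB3 and HMOX1 among the members called higher. The lists of cholesterol synthesis, collagens and matrix, and integrins had lower medians, with 5 to 8 members of each called lower. Those of DNA replication and mitosis also had lower medians, with no member called. Of 13937 tested genes, 640 (4.59%) were at least 2-fold higher and 532 (3.82%) at least 2-fold lower in the resistant library. Of these, 61 and 59 were at least 4-fold higher and lower. The median log2 fold over all tested genes was 0.04.

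Among genes named by the rule, the highest fold with the pseudocount of 1 was that of FHL2, a LIM-domain cofactor of transcription. FHL2 (ENSG00000115641, chromosome 2, 105357712 to 105438513, GRCh38) had 1.03 FPKM in the parental and 29.1 in the resistant library (log2 fold 3.89). By the plain FPKM ratio, MMP3 rose more. The matrix protease MMP3 had 0.146 and 9.39 FPKM (3.18), complement component C3 had 1.10 and 16.8 (3.09), and the TNF-family ligand CD70 had 9.46 and 67.5 (2.71). The receptor tyrosine kinase MET had 9.38 and 74.6 FPKM (2.86). The hexokinase-related gene HKDC1 had 10.3 and 92.3 (3.05), and ANKRD1, a target of YAP signalling, had 27.9 and 182 (2.66). The keratin KRT81 had 17.3 and 186 FPKM (3.35), and its value is uncertain because closely similar hair keratin genes can share its reads. The readthrough gene ATP6V1G2-DDX39B (0.650 and 9.22 FPKM) is uncertain as well, since it shares exons on the same strand with DDX39B, which had 113 and 96.0.

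The lowest of the named genes with the pseudocount of 1 was GPM6A, a neuronal membrane glycoprotein. GPM6A (ENSG00000150625, chromosome 4, 175632934 to 176002664, GRCh38) had 98.9 FPKM in the parental and 0.482 in the resistant library (log2 fold -6.08). By the plain FPKM ratio, HAPLN1 and FSTL5 fell further. The chemokine CCL2 had 50.8 and 0.840 FPKM (-4.81). The hyaluronan link protein HAPLN1 had 26.1 and 0.0392 FPKM (-4.71) and periostin, POSTN, 46.1 and 2.83 (-3.62). FSTL5 had 18.2 and 0.0125 FPKM (-4.25), the somatostatin receptor SSTR2 had 20.8 and 1.14 (-3.35), and the kinase MAP3K8 had 31.7 and 2.25 (-3.33). LRIG3 had 58.2 and 5.52 FPKM (-3.18). RGS5, a regulator of G-protein signalling known from pericytes, had 22.8 and 1.55 FPKM (-3.22), and it shares exons with a second listed gene of the same name at 1.87 and 1.60. The readthrough gene BLOC1S5-TXNDC5 (20.4 and 0.658 FPKM) is uncertain, since it shares exons with TXNDC5, which had 29.2 and 51.6.

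**Figure D1:**
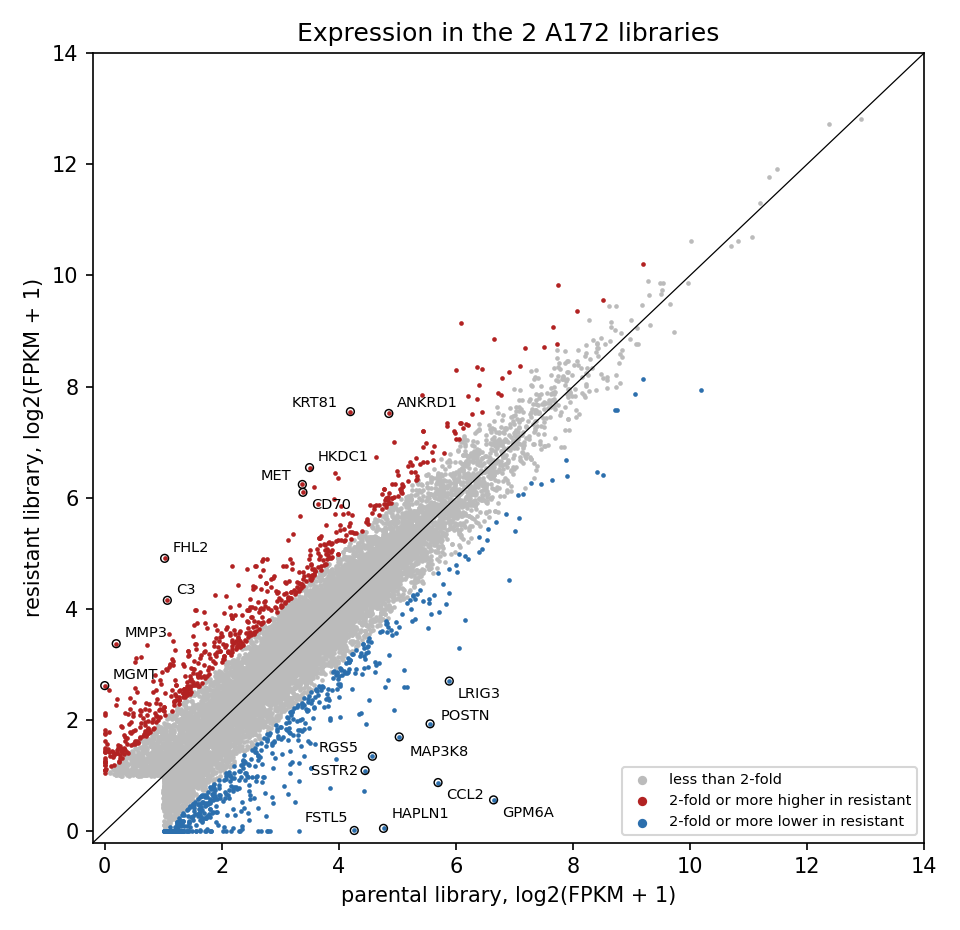
Expression of the tested genes in the parental (x axis) and resistant (y axis) library, each as log2(FPKM + 1); every point is a gene, XIST and Y-linked genes left out, and circles mark MGMT and the genes with the largest folds that the text names, readthrough genes left out. The 640 genes at least 2-fold higher in the resistant library are red and the 532 lower ones blue; GPM6A (98.9 and 0.482 FPKM) lies farthest below the diagonal, and MGMT is listed at 0 on the x axis.

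DNA repair genes were examined first because temozolomide kills cells through alkylated guanine and mismatch repair. MGMT (ENSG00000170430) lies on chromosome 10 from 129467184 to 129768007 (GRCh38, plus strand), and no other listed gene shares its exons. The mismatch repair genes MSH6, with 17.2 FPKM in the parental and 17.4 in the resistant library, and PMS2, with 18.6 and 26.2, stayed under the 2-fold threshold. MSH6 shares exons with FBXO11 on the opposite strand. None of the 21 measured mismatch repair genes was called, and their median log2 fold was -0.13, inside the random band (percentile 5.14). Of 20 direct reversal and base excision repair genes only MGMT was called higher and none lower, with ALKBH2 at 4.16 and 7.65 FPKM and XRCC1 at 9.48 and 5.53 (median -0.02, percentile 30.6). Homologous recombination and Fanconi anemia genes were lower as a list (median -0.19, percentile 1.53), with 2 of 31 called lower, RAD54L (6.07 and 2.39 FPKM) and FANCA (16.9 and 7.74), and none higher.

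Among stress and survival genes, 9 of 25 p53 targets were called higher and none lower. Their median log2 fold of 0.60 exceeded that of all 10000 random lists. The growth arrest gene GADD45A had 14.2 FPKM in the parental and 85.9 in the resistant library, the cyclin-dependent kinase inhibitor CDKN1A had 56.7 and 155, and MDM2, the ubiquitin ligase of p53, had 26.3 and 70.4. The unfolded protein and ATF4 list had 10 of 29 members higher and none lower (median 0.70, above all random lists), with TRIB3 at 23.9 and 106 FPKM, PPP1R15A at 11.6 and 38.0 and ATF3 at 11.6 and 37.7. Of 25 NRF2 and glutathione genes, 6 were higher and 2 lower (median 0.42, percentile 99.7). SRXN1 had 8.25 and 40.0 FPKM, heme oxygenase HMOX1 had 5.53 and 25.0, and thioredoxin reductase TXNRD1 had 144 and 412. In the BCL2 list, which also holds inhibitors of apoptosis outside that family such as BIRC5, 2 of 17 were higher and 1 lower (median 0.37, percentile 98.6). The proapoptotic HRK had 0.928 and 5.63 FPKM, BCL2 had 1.56 and 4.87, and the proapoptotic BCL2L11 was lower, at 18.6 and 6.57. With a filter of 5 FPKM the BCL2 list lay inside the band.

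Signalling lists above the band held members in both directions. Of 12 NF-kB and cytokine genes, 3 were higher and 1 lower (median 0.56, percentile 99.9), with RELB at 2.49 FPKM in the parental and 7.71 in the resistant library, IL11 at 2.42 and 8.14, and CCL2 lower. The MAPK and serum response list had 6 of 24 higher and 4 lower (median 0.41, percentile 99.9). MYC had 4.99 and 26.2 FPKM and FOSL1 1.98 and 12.5, while FOS had 4.23 and 0.336 and SPRY2, a feedback inhibitor of the pathway, 15.2 and 3.14. Cytosolic ribosomal proteins were higher as a list, with 1 of 39 called higher, RPS2 (362 and 754 FPKM), and none lower (median 0.38, percentile 99.6); the many processed copies of these genes can share their reads. Of 8 cancer-testis antigens, 4 were higher and 1 lower (median 0.64, percentile 99.5). SSX2 had 0.158 and 4.20 FPKM, MAGEB2 and PAGE1 were listed at 0 in the parental and at 3.40 and 2.41 FPKM in the resistant library, and members of these families have near-identical copies. With no filter on low values the median of that list was 0.08, and without genes at 0 in 1 library it was -0.31, both inside the band.

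Cholesterol and fatty acid synthesis was the list with the most genes called lower, 8 of 29, with none higher. Its median of -0.68 was below that of all 10000 random lists. Squalene synthase FDFT1 had 128 FPKM in the parental and 41.4 in the resistant library, HMGCS1 had 85.9 and 32.8, MSMO1 had 73.1 and 28.7, and HSD17B7 had 15.0 and 4.33. Of 27 collagen and matrix genes, 5 were lower and none higher (median -0.23, percentile 0.16). COL1A2 had 1165 and 245 FPKM, COL1A1 33.5 and 6.53, and fibrillin FBN1 362 and 83.8. Of 14 integrins, 5 were lower and none higher (median -0.40, percentile 0.27), with ITGA11 at 6.31 and 0.433 FPKM and ITGA4 at 30.5 and 10.9. The clustered protocadherins, cell adhesion genes read from neighbouring promoters, had 5 of 22 lower and none higher (median -0.56, percentile 0.02), with PCDHGC3 at 64.1 and 24.5 FPKM. Members of some protocadherin clusters can share exons.

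Proliferation genes were lower as lists with no single member called. The pseudocount of 1 kept some members under the threshold, such as KIF20A below, whose plain FPKM ratio exceeded 2-fold. None of 27 G1/S and DNA replication genes was called (median -0.34, percentile 0.03), with PCNA at 66.5 FPKM in the parental and 33.8 in the resistant library and RRM1 at 54.7 and 30.9. None of 30 G2/M genes was called either (median -0.32, percentile 0.02), with KIF20A at 19.2 and 9.47 and PRC1 at 50.4 and 25.8. The replication-dependent histones, whose mRNAs mostly lack a poly(A) tail, had a median of -0.45 over 20 genes, below all random lists, with HIST1H1B at 87.8 and 46.9 FPKM and none called. None of 34 nuclear-encoded respiratory chain genes was called (median -0.15, percentile 0.63), with NDUFB8 at 29.7 and 15.4 FPKM. Of 30 chromatin and DNA methylation enzymes, 1 was lower, HDAC5 (17.0 and 6.61 FPKM), and none higher (median -0.15, percentile 1.87). That list lay inside the band with a filter of 5 FPKM and with matching on length.

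The remaining lists of pathways lay inside the random band. Mesenchymal genes were split, with 9 of 27 higher and 2 lower (median 0.03, percentile 31.2), SNAI2 at 4.96 FPKM in the parental and 26.3 in the resistant library and ACTA2 at 0.945 and 5.30, beside the lower POSTN. With a filter of 5 FPKM their median was 0.39, above the band. In the TGF-beta and BMP list 6 of 22 were higher and 2 lower (median 0.26, percentile 96.7), with the receptor TGFBR2 lower, at 65.4 and 8.83 FPKM, and ID3 higher, at 8.73 and 21.5. This list also lay above the band with the 5 FPKM filter, at 0.61. Of 22 Wnt genes, 5 were higher and 4 lower (median 0.30, percentile 97.4), with WNT7B at 0.544 and 7.75 FPKM and WNT5A at 21.7 and 6.82. Its median moved to -0.05 with the 5 FPKM filter and lay above the band under 5 other settings. Among 26 receptor tyrosine kinases and ligands, 6 were higher and 1 lower (median 0.18, percentile 84.2), with EPHA2 at 14.3 and 51.2 FPKM and EPHA4 at 38.2 and 13.1.

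Of 11 drug efflux transporters, the cholesterol transporters ABCA1 (14.8 FPKM parental, 80.5 resistant) and ABCG1 (2.71 and 12.05) were higher and none lower (median 0.00, percentile 31.1). Of 24 autophagy genes, MAP1LC3B (35.3 and 94.1) and SQSTM1 (588 and 1180) were higher and none lower (median 0.01, percentile 27.7). Of 27 hypoxia and glycolysis genes, VEGFA (38.6 and 87.3) was higher and STC1 (2.45 and 0.241) lower (median 0.03, percentile 34.0). Of 12 aldehyde dehydrogenases, ALDH1A3 (1.33 and 5.23) was higher and none lower (median -0.14, percentile 13.6). Interferon-stimulated genes had 2 of 33 higher and 1 lower (median 0.20, percentile 95.2), with IFI27 at 2.64 and 9.09 and IFI44 at 10.2 and 4.39. None of 14 antigen presentation genes was called (median 0.34, percentile 94.8), with B2M at 848 and 507. HOX genes had 2 of 24 higher and 1 lower (median -0.02, percentile 40.2), with HOXB9 at 5.79 and 21.1 and HOXA10 at 15.9 and 6.41. Of 17 glioma long noncoding RNAs, 3 were higher and 1 lower (median 0.19, percentile 81.6), with GAS5 at 80.8 and 218 and LINC00511 at 7.84 and 2.91. None of the 13 mitochondrially encoded genes was called (median 0.19, percentile 65.5). None of 15 reference genes was called, and their log2 folds ran from -0.74 for B2M to 0.61 for EEF1A1 (median 0.08, percentile 44.1).

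**Figure D2:**
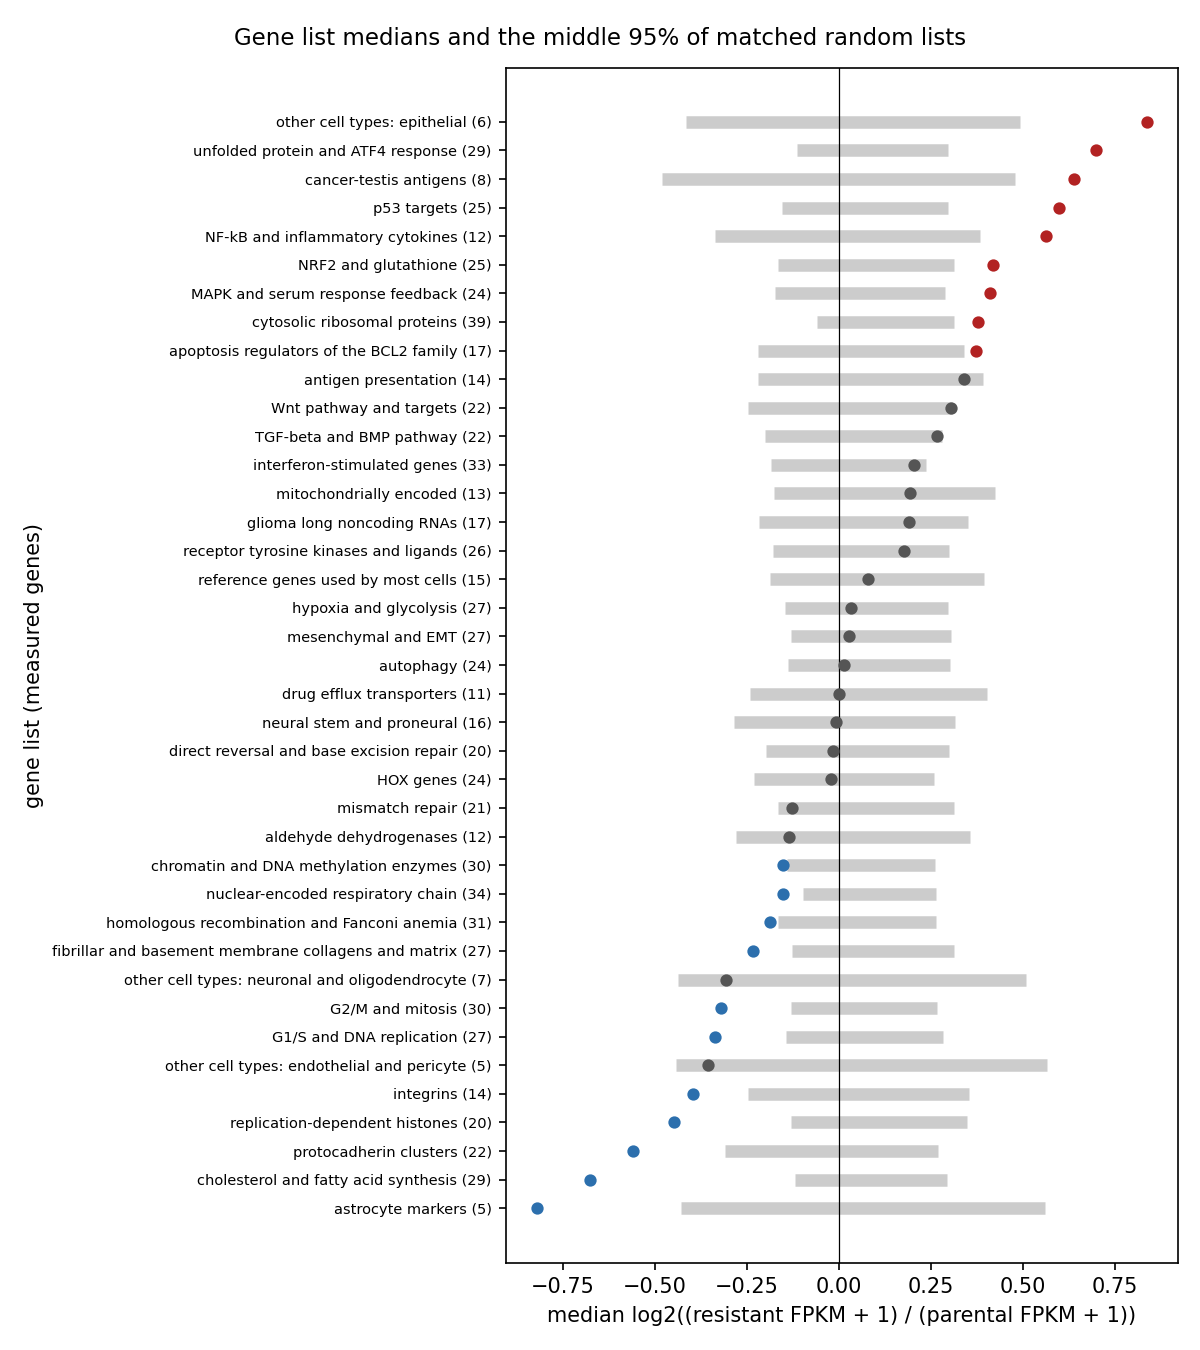
Median log2((resistant FPKM + 1)/(parental FPKM + 1)) of each fixed gene list with 5 or more measured genes (dots, number of genes in parentheses) and the middle 95% of the medians of 10000 random lists matched on mean expression (grey bars). Of 39 lists, 9 lie above their bar (red), 11 below (blue) and 19 within (dark grey); 20 genes are in more than 1 list, so the lists are not independent.

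Cell type markers were read as levels only. Neural stem and proneural genes had 3 of 16 lower and 1 higher (median -0.01, percentile 42.8), with nestin, NES, at 33.7 FPKM in the parental and 5.08 in the resistant library and SOX2 at 2.23 and 0.253. The 5 measured astrocyte markers were below the band (median -0.82, percentile 0.09), none called, with CLU at 101 and 53.3 and GLUL at 38.0 and 19.9. Of 6 epithelial genes, KRT8 (213 and 905 FPKM) and ESRP1 (0.515 and 2.25) were higher and none lower, and KRT18 had 392 and 702 (median 0.84, percentile 99.9). With no filter on low values that median was -0.11, inside the band. Of 5 endothelial and pericyte genes, RGS5 and TEK (9.53 and 1.56 FPKM) were lower and none higher (median -0.36, percentile 5.24). None of 7 neuronal and oligodendrocyte genes was called (median -0.31, percentile 7.22), with the neurofilament NEFL at 61.9 and 31.5. Of the myeloid and lymphoid genes only PTPRC was measured, at 1.83 and 0.485 FPKM.

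Levels by chromosome were compared because a clone can differ in copy number from its parent. Below the random band lay chromosome 13, with a median log2 fold of -0.23 over 231 genes, chromosome 3 (-0.17, 783 genes) and chromosome 15 (-0.13, 456 genes). Chromosomes 17 (-0.03) and 2 (-0.01) also lay below it, with a change of sign under the 5 FPKM filter. Above the band lay chromosomes 7 (0.15), 4 (0.14), 20 (0.14), 6 (0.11), 16 (0.10), 9 (0.10), 5 (0.09) and 11 (0.09). Chromosome 10 as a whole was inside it (0.00, percentile 8.59). Chromosomes 9, 11 and 16 came inside the band under at least 1 alternative.

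Around MGMT, in a segment chosen after its values were seen, the genes from ATE1 to the end of 10q (121740421 to 133421307, GRCh38) had a median log2 fold of -0.65 over 44 genes, below all random sets. Of these, 8 were called lower and 1, MGMT, higher, and 39 had a negative fold. Of the genes named here, also chosen after their values were seen, OAT had 27.4 FPKM in the parental and 12.5 in the resistant library, HTRA1 had 9.60 and 2.60, and MKI67 had 10.6 and 4.85. STK32C, LRRC27 and FUOM were listed at 0 in the resistant library and at 3.95, 1.96 and 1.64 FPKM in the parental one. GLRX3, the next listed gene after MGMT, had 30.4 and 49.2 FPKM, and BNIP3 had 3.89 and 7.99. The 44 genes just before the segment had a median of 0.20.

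**Figure D3:**
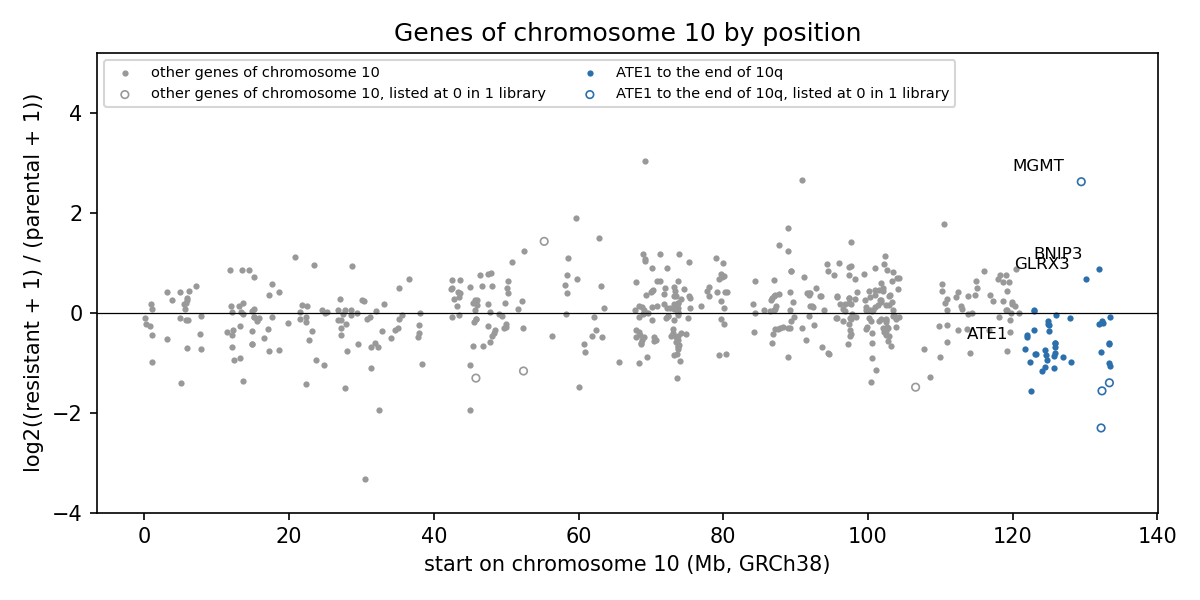
Log2((resistant FPKM + 1)/(parental FPKM + 1)) of the tested genes of chromosome 10 against gene start (Mb, GRCh38); open circles are genes listed at 0 in 1 library, for which the plotted height depends on the pseudocount. The 44 genes from ATE1 to the end of the long arm (blue) have a median of -0.65, and MGMT, GLRX3 and BNIP3 lie above 0 among them.

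In the authors' deposited table, 801 genes with a q-value under 0.05 were higher and 621 lower in the resistant library, a threshold chosen here. Of these genes, 1322 passed the filter on low values, and 840 of them differed at least 2-fold. In the authors' deposited table the q-value was 0.00774 for MGMT, 0.985 for MSH6 and 0.520 for PMS2. A test on 2 libraries compares those libraries, not the conditions.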

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

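Settings named in processing as alternatives were planned, except matching on GC content, leaving out genes at 0 in 1 library, upper quartile scaling for the lists, the chromosome medians under scaling, pseudocount and no filter, and all values of distal 10q, which were chosen after seeing the data. The counts of genes depended most on the threshold and the pseudocount. At 1.5-fold, 2020 genes were higher and 1674 lower, and at 4-fold 61 and 59. A pseudocount of 0.1 gave 1076 higher and 1029 lower, and 0.01 gave 1134 and 1083, since a smaller pseudocount leaves more of the fold of low genes. A filter of 5 FPKM, under which fewer genes were tested, left 282 lower and 466 higher. It removed more lower than higher calls, so that 62.3% of the calls were higher, against 54.6% in the main setting. In the main setting 551 of the 640 higher and 370 of the 532 lower genes were protein-coding. Median centring gave 569 higher and 587 lower and upper quartile scaling 533 and 607, so that the direction with more genes depended on the scaling. Without genes at 0 in 1 library, 617 were higher and 470 lower. Median centring cannot move a list or chromosome across its random band and is left out of the counts of list, chromosome and distal 10q medians. Of 308 list medians recomputed, 295 kept their side of the random band, 6 came inside and 7 left it. Of 144 chromosome medians, 134 kept theirs. Single folds were recomputed only for mismatch repair genes and for the 10 highest and 10 lowest genes, and not for other list members such as KIF20A. All 96 of these folds kept their side of 2-fold. The 6 values of distal 10q stayed below the band. No list, chromosome or named gene recomputed here reversed from one side to the other. Alternatives that need counts (TMM, DESeq2 size factors, total counts, count filters and count pseudocounts) could not be run on FPKM. No paired analysis was possible because each group held 1 library, and none could be left out. Depth is unknown, so it is not known which low values counting error limits.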

Other observations

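All gene lists in the next 2 paragraphs were chosen after results were seen, as was the list of small nucleolar RNA host genes. So was every test below except that of the liver X receptor targets.

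Targets of YAP and TAZ, coactivators that respond to cell shape and matrix stiffness, had 7 of 21 measured members at least 2-fold higher in the resistant library and none lower. Their median log2 fold of 0.73 exceeded that of all 10000 matched random lists. Tissue factor, F3, had 9.12 FPKM in the parental and 49.8 in the resistant library, WWC1 had 3.11 and 14.2, and CYR61 had 47.4 and 112. ANKRD1, which was already among the genes with the highest folds, is a member. Of 21 secreted proteases of the matrix and their inhibitors, 4 were higher and none lower, with MMP13 at 0.695 and 3.53 FPKM, the plasminogen activator PLAU at 3.72 and 9.74 and the inhibitor TIMP3 at 11.8 and 34.5. That list's median of 0.09 lay inside the random band (percentile 60.9).

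Zinc finger genes of chromosome 19 were lower as a list, with 3 of 30 called lower and none higher (median -0.33, percentile 0.41). ZNF226 had 11.2 and 4.80 FPKM and ZNF461 6.37 and 2.80. The random lists were not matched on position, so gene family and place on the chromosome cannot be told apart here. The lowest windows of 100 adjacent genes lay on chromosome 17 (3802165 to 8383187, median -0.36), chromosome 19 (39436156 to 45305283, -0.32) and chromosome 13 (46125920 to 108218368, -0.32). The highest lay on chromosome 6 (118894220 to 152759765, 0.38).

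The lower levels of distal 10q, around a higher MGMT, were weighed first. Matching on GC content or length left the segment at percentile 0, with the lower limit of random sets at -0.20 under both. Genes alike in either property were thus not as low in general. The segment was chosen for its low values and the random sets were not, so the percentile itself decides little. Leaving out members of the fixed lists kept 41 of its 44 genes, with a median of -0.69. Too few genes were left out for this to decide on the listed functions. The last 44 genes of 0 of the 22 other chromosomes had a median as low, the lowest being -0.27. That length was set by the low run of 10q itself, which favours 10q. An earlier form of this test with 100 genes, which dilutes the segment, had put 2 chromosomes as low as 10q (-0.16). That number would meet the bound of 2 used for an effect of chromosome ends. The 2 were chromosomes 13 (-0.26) and 3 (-0.18), which were also low as a whole (-0.23 and -0.17), so their low ends need not be an effect of position. Medians of the last 44 genes ran up to 0.31, on chromosome 6. The test was changed after its first result was seen, so it leaves position near a chromosome end undecided. With the boundary searched on every other gene of the arm, 90.9% of the 22 left-out genes beyond it lay below the median of all genes, against 42.8% of those before it, but all 22 were in the segment already seen to be low, so the value decides nothing on a lower copy number. Copy number was not measured, silencing of the region was not tested, and a loss alone would leave MGMT, GLRX3 and BNIP3 as exceptions, beside C10orf88 and PSTK with folds near 0 (log2 fold 0.05 and 0.03).

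Small nucleolar RNA host genes, which carry these RNAs in their introns, were higher in the resistant library (4 of 22 called higher and 1 lower, median 0.62, above all random lists), with SNHG8 at 16.9 and 52.0 FPKM and SNHG15 at 10.4 and 32.4. A larger share of RNA without a poly(A) tail or from introns would raise classes of either kind, but those examined went apart. Histones had a median of -0.45, sense-intronic genes -0.29 and 39 structural noncoding RNAs 0.18 (percentile 89.8). The replication-dependent histones were lower beside the DNA replication list (median -0.34). Long intergenic (-0.18) and antisense (-0.11) RNAs also had negative medians. The lower histone and sense-intronic medians therefore need not reflect tail status. Of the 14 structural RNAs with 10 or more FPKM in either library, 12 had a positive fold, with RMRP at 63.1 and 315 FPKM. Related copies among these, such as RN7SL2 and RN7SL5P, can share reads. Of all 39, 7 were called higher, 2 of them listed at 0 in the parental library. All 5 called lower were listed at 0 in the resistant library, so the explanation stays open. Weaker nonsense-mediated decay may contribute and stays open: the 7 decay factors that are themselves decay targets had a median of 0.24 (percentile 77.5), 6 of them with a positive fold. Higher levels of the translation machinery as a whole stay open as well, since 15 translation factors with a terminal oligopyrimidine tract had a median of 0.40 (percentile 96.8), 14 of them with a positive fold.

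Cholesterol synthesis genes were lower while ABCA1 and ABCG1, which export sterols, were higher. GC content or length did not account for it, as the list stayed at percentile 0 under both matchings. A sterol load could lower synthesis genes and raise targets of the liver X receptor. The 5 other targets examined, a test written before their values were seen, had a median of -0.16 (percentile 31.5). Of these, 1 had a positive fold, SMPDL3A (1.35 and 2.98 FPKM). The other 4 had a negative fold, NR1H3 (7.73 and 4.19 FPKM) among them, and none was called. The median met the bound set against a sterol load, but random lists of 5 genes ran from -0.58 to 0.54, so the explanation is not excluded.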
